A study of Homo sapiens with 52 samples.

How the data were processed

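RNA from primary human bronchial epithelial cells was measured on Affymetrix Human Exon 1.0 ST arrays, which carry probes along the exons of each gene. The cells came from 3 never smokers, were pooled, and were infected with an adenovirus carrying ATM, BCL2, GPX1, IKBKB, NOS2, SIRT1 or, as the control, green fluorescent protein (GFP). RNA was taken 18 hours after infection. The authors deposited 1 RMA intensity per gene and array on the linear scale, computed with a chip definition file that groups probes by Entrez Gene identifier. RMA (robust multi-array average) corrects background, normalizes the arrays to each other and summarises the probes of a gene; it is named without a version in the submitters' processing notes. Background correction and summarisation pull the values of weakly expressed genes toward a floor, so that changes near it are measured as smaller than they are.

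The deposited values covered 23536 genes on 52 arrays. Of these, 20727 carried 1 current symbol in the NCBI gene annotation and 2809 were not named here, although they stayed in every test. Values were put on the log2 scale with no filter and no further normalization. The array medians lay between 48.9 and 64.8 on the linear scale and the lower quartiles between 21.2 and 33.9. For arrays there is no read depth, and their number limits the precision. No pair of arrays held the same values, and the correlation between 2 arrays across genes lay between 0.811 and 0.993.

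The comparisons used the 39 arrays that the authors kept, in the batches labelled 1, 2 and 4. The authors left out 13 arrays. They named low correlation between samples for 1 SIRT1 array, and a strong batch effect seen by principal components for the 12 arrays of batch 3. Replicate numbers did not pair arrays across groups, since arrays with the same number often sat in different batches and their residuals correlated between -0.71 and 0.69.

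A linear model with the 7 groups and the 3 batches as fixed terms was fitted to each gene with limma 3.58.1 in R 4.3.3 (lmFit and eBayes). It had 30 residual degrees of freedom and 4.71 prior degrees of freedom. Each construct was compared with GFP, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Adjusted p-values of single genes are from limma and 2-sided. Means are given with the SD between arrays, and log2 differences with the standard error (SE) of the fit. The p-values measure only the spread between cultures of 1 donor pool, so they say nothing about the spread between people. Each construct was also compared with the mean of the other 5 constructs, and with the mean of all 6 other groups. The same fit gave GFP against the mean of the 6 constructs, a comparison added after the data were seen.

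Gene lists were tested with camera, in which each gene of a list is set against all other genes, with a preset correlation between genes of 0.01. The 28 lists held 596 members, of which 549 had a value, and the gene carried by the virus was taken out of every list. P-values were adjusted over the 168 tests of 28 lists in 6 comparisons. Camera with an estimated correlation and fry were alternatives; fry tests whether the genes of a list move, on balance, one way, without comparing them with other genes. List members were counted as raised or lowered at the adjusted p over all genes, and also adjusted over the list alone. List tests against the other 5 constructs were added after the data were seen.

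The genes to be named were set by rule for each construct. The rule took the gene carried by the virus, and the 8 raised and 8 lowered genes with the largest change among those past the threshold whose difference had the same sign in batches 1, 2 and 4. It also took up to 4 passing members, by size of change, of each list whose camera test passed or of which at least 3 members passed. The groups, the arrays used, the tests against GFP, the gene lists, the rule for naming and the alternatives were set before the data were examined, except where they are described as added. Symbols of genes outside the rule are identified as chosen after their values were seen.

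The correlation of 2 responses is raised by the control arrays they share, so data were simulated 100 times with no effect and the same shared controls, and the correlations were also computed with the GFP arrays split between the responses. The procedure was tested on simulated data in which 100 genes were shifted at each of 2 sizes. At a shift of 0.5 log2 it recovered 60 (ATM), 69 (BCL2), 72 (GPX1), 65 (IKBKB), 65 (NOS2) and 67 (SIRT1) of them, and at a shift of 1 log2 between 95 and 100. Unshifted genes called were 9, 5, 9, 10, 14 and 9, of 164, 173, 181, 173, 176 and 172 calls at both sizes together. Genes were drawn independently of each other in these simulated data, without the variation that genes of a real array share. These counts therefore need not hold for the real arrays. Alternatives were quantile normalization, median centring, leaving out dim genes, array weights, the lower quartile of each array as a covariate, no batch term, batch as a random term, a replicate block, only the arrays of 1 construct and GFP, all 52 arrays, each batch alone, and leaving out each array in turn. Each count was also set against 100 random splits of the same arrays. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.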

Results

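Bronchial epithelial cells pooled from 3 donors who had never smoked were infected with adenoviruses to ask which genes respond when a pathway linked to tobacco smoke exposure is switched on in airway epithelium. The 6 virus-borne genes were ATM, the kinase that signals DNA breaks; BCL2, an inhibitor of apoptosis; GPX1, a glutathione peroxidase; IKBKB, the kinase that frees NF-kB from its inhibitor; NOS2, the inducible nitric oxide synthase; and SIRT1, an NAD-dependent deacetylase. GFP virus was the control. Of 52 arrays, 8 were GFP, 7 ATM, 8 BCL2, 8 GPX1, 7 IKBKB, 7 NOS2 and 7 SIRT1. The 39 arrays compared here were 6 GFP, 5 ATM, 6 BCL2, 6 GPX1, 6 IKBKB, 5 NOS2 and 5 SIRT1. Each of batches 1, 2 and 4 held every group, with 1 to 4 arrays of it.

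The level of each virus-borne gene was compared first. NOS2 (Entrez Gene 4843) stood at 11.28 ± 0.09 log2 units (SD, n = 5) on NOS2 arrays and at 4.86 ± 0.16 (n = 6) on GFP arrays, an 85.1-fold rise (adjusted p = 6.4e-34). BCL2 (596) rose 3.39-fold, from 4.82 ± 0.16 to 6.57 ± 0.17 (n = 6 and 6, adjusted p = 2.5e-15). On GFP arrays both stood near the lower quartile of all genes, 4.73 ± 0.09 (n = 6), so both folds rest on GFP levels that were not clearly above background. IKBKB (3551) rose 1.39-fold, from 7.53 ± 0.09 to 8.01 ± 0.09 (n = 6 and 6, adjusted p = 2.8e-06), and the lowest IKBKB array, at 7.86, lay above the highest of the 33 other arrays, at 7.77. SIRT1 (23411) rose 1.26-fold, from 6.71 ± 0.13 (n = 6) to 7.05 ± 0.15 (n = 5, adjusted p = 0.0088); against the other 5 constructs the difference was 0.23 log2 (adjusted p = 0.068), and without SIRT1 replicate 5 the difference from GFP was 0.29 and did not pass. ATM (472) did not pass, at 7.06 ± 0.28 (n = 5) against 6.70 ± 0.26 (n = 6), a difference of 0.33 ± 0.17 log2 (SE; 95% interval -0.0028 to 0.67, adjusted p = 0.44). Its difference was 0.72 in batch 1, 0.46 in batch 2 and -0.042 in batch 4. GPX1 (2876) did not pass either, at 8.82 ± 0.18 against 8.94 ± 0.09 (n = 6 and 6), a difference of -0.12 ± 0.07 (adjusted p = 0.54). The GPX1 pseudogene GPX1P1 (441481), which resembles GPX1 in sequence and was chosen as the largest rise on those arrays, rose 14.5-fold, from 7.50 ± 0.37 to 11.36 ± 0.20 (n = 6 and 6, adjusted p = 2.6e-16). The groups are therefore called by their labels for ATM and GPX1.

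**Figure D1:**
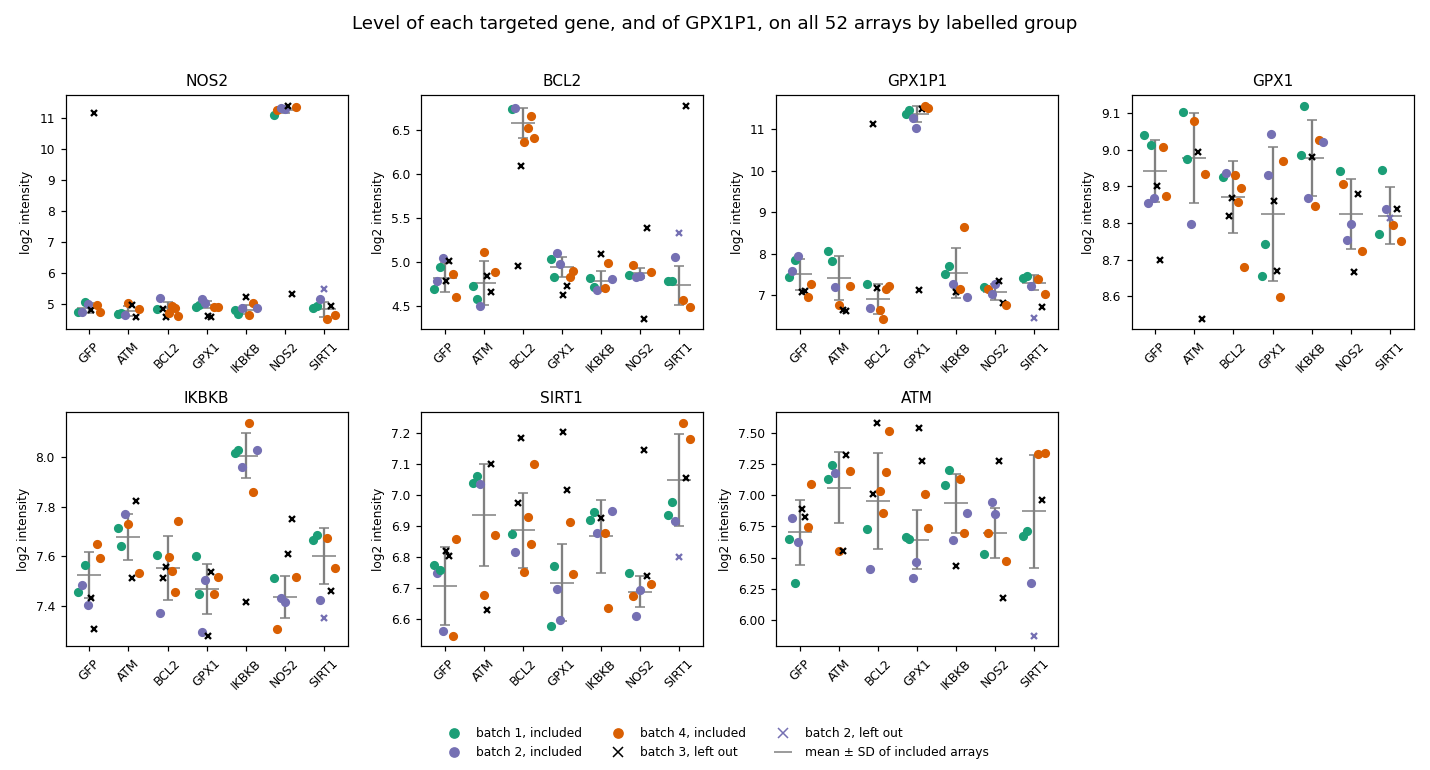
Level of each virus-borne gene and of GPX1P1 (log2 RMA intensity) on all 52 arrays, by labelled group, with included arrays as circles coloured by batch, arrays left out as crosses, and bars for the mean ± SD of the included arrays. The included NOS2 arrays sit between 11.13 and 11.36 and the other included arrays at or below 5.18 for NOS2, the included groups overlap for ATM, GPX1 and SIRT1, and several crosses of batch 3 lie at the level of another group.

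All 6 constructs were separated from the GFP control by heat shock genes. HSPA1A, an inducible HSP70 chaperone, was 5.04-fold higher on GFP arrays than on the mean of the construct arrays (2.33 ± 0.15 log2, SE, n = 6 against 33, adjusted p = 5.4e-14). DNAJA4, a co-chaperone, was 4.57-fold higher, HSPA1B, a near-identical copy of HSPA1A, 4.11-fold, and CRYAB, a small heat shock protein, 3.98-fold. CRYAB stood at 5.03 ± 0.33 on the construct arrays (SD, n = 33), near the lower quartile of all genes, so its differences rest on a level near background. Of the 15 heat shock genes, 14 were higher in GFP and 1 did not pass (median 0.63 log2, adjusted p = 6.4e-53, and adjusted p = 1.3e-06 with an estimated correlation). Between 11 and 14 of the 15 fell in each construct against GFP. The small nucleolar RNAs SNORD14C, SNORD14D and SNORD14E, which lie inside the HSP70 family gene HSPA8, were 1.30, 1.31 and 1.51 log2 higher in GFP. DUSP1, a stress-induced phosphatase named after its values were seen, was 1.04 ± 0.08 log2 higher.

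Genes of cell division were lower on GFP arrays. TOP2A, the topoisomerase of dividing cells, differed by -0.81 ± 0.12 log2, MKI67, the Ki-67 proliferation antigen, by -0.69 ± 0.07, RRM2, a subunit of ribonucleotide reductase, by -0.67 ± 0.07 and ANLN, a cytokinesis protein, by -0.74 ± 0.12 (SE, n = 6 against 33). Of 23 mitotic genes 19 were lower in GFP, 1 was higher and 3 did not pass (median -0.41, adjusted p = 8.5e-32). The 23 DNA replication genes split into 10 lower, 2 higher and 11 not passing (adjusted p = 3.0e-11). NF-kB target genes were lower for 9 of 30 (adjusted p = 5.5e-09) than in a mean that includes IKBKB, where 14 of the 30 rose; in GPX1 none passed, and in NOS2 2 rose and the list did not pass (adjusted p = 0.16). Lower in GFP were also 7 of 20 matrix and TGF-beta response genes (adjusted p = 1.4e-06). The p53 target list was higher in GFP, with 4 of 23 higher and 1 lower (adjusted p = 4.2e-05). Falls of that list in single constructs against GFP share this difference and are not independent. With an estimated correlation these calls of GFP against the constructs held, but at larger values. They were adjusted p = 1.3e-04 (mitotic), 1.6e-05 (replication), 3.9e-06 (NF-kB), 0.018 (matrix) and 0.033 (p53). The call of the DNA damage genes, with 6 of 23 lower (adjusted p = 1.6e-07), did not hold (adjusted p = 0.066 with an estimated correlation). In all, 1219 genes differed, 654 higher and 565 lower in GFP. Without GFP replicate 3 the count was 807.

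Against GFP, 83 genes were lowered and 37 raised in all 6 constructs, and 981 of the 2105 genes called in any construct were called in 1 only. Many of the calls also separated GFP from the mean of the 6 constructs, in the matching direction. The shares were 78.9% (ATM), 77.1% (BCL2), 87.9% (GPX1), 86.7% (IKBKB), 79.1% (NOS2) and 61.4% (SIRT1). The same GFP arrays enter both comparisons, so a change against GFP need not be particular to 1 construct. Across genes, which are not independent replicates, the 15 pairs of responses correlated at a median r of 0.56 (0.20 to 0.78; Spearman 0.51). Simulated data with no effect and the same shared GFP arrays gave a median r of 0.45, with single simulated pairs from -0.64 to 0.94. With the GFP arrays split between the responses the median r was 0.28 (0.0050 to 0.46). The median covariance was 0.0145, against 0.0055 in the simulation. A median of 127 genes rose in both members of a pair and 203 fell in both, counts that the shared GFP arrays raise by an amount that was not estimated.

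On the arrays labelled ATM, genes of the cell cycle rose. TOP2A rose by 0.94 ± 0.16 log2 (SE, n = 5 against 6), MKI67 by 0.82 ± 0.09, RRM2 by 0.78 ± 0.09, and CENPI and CENPF, centromere proteins, by 0.81 ± 0.13 and 0.80 ± 0.13. Of 23 mitotic genes 16 rose, none fell and 7 did not pass (20 adjusted over the list alone, median 0.56, adjusted p = 9.3e-39), and 6 of 23 replication genes rose (16 adjusted over the list alone, adjusted p = 8.0e-14). With an estimated correlation these 2 lists had adjusted p = 5.7e-05 and 8.9e-06. DNA damage response genes rose for 4 of 23 (9 adjusted over the list alone, adjusted p = 6.8e-11, and adjusted p = 0.024 with an estimated correlation). FANCI and BRCA1, of interstrand crosslink and recombination repair, rose by 0.59 ± 0.11 and 0.42 ± 0.09, EXO1, an exonuclease, by 0.49 ± 0.08, and BLM, a helicase, by 0.36 ± 0.05. BLM rose in all 6 constructs and stood below the lower quartile of all genes, at 3.77 on GFP arrays and at most 4.34 on construct arrays. Against the other 5 constructs this list was higher with no member passing (median 0.08, adjusted p = 0.0051, and adjusted p = 0.45 with an estimated correlation). NF-kB targets rose for 5 of 30 (7 adjusted over the list alone, adjusted p = 3.0e-06), among them CXCL8, a neutrophil chemokine, by 0.47 ± 0.08. CRYAB fell by 2.27 ± 0.14 to a level near background, with 11 of 15 heat shock genes lowered (14 adjusted over the list alone, adjusted p = 3.6e-41).

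The p53 target list was lower on ATM arrays (adjusted p = 0.011, and adjusted p = 0.23 with an estimated correlation), with GDF15, a stress cytokine, falling by 0.54 ± 0.09 and SESN2, a stress-induced regulator of mTORC1, by 0.50 ± 0.07. Of its 23 genes 1 rose, 2 fell and 20 did not pass. Squamous differentiation genes fell for 2 of 22 (adjusted p = 0.0014, and adjusted p = 0.38 with an estimated correlation). NRF2 targets, with SLC7A11 falling by 0.68 ± 0.15 as 1 of 22, and cholesterol synthesis genes, of which no member passed in limma, also passed camera (adjusted p = 0.044 and 0.0043, and adjusted p = 0.60 and 0.37 with an estimated correlation). Against the other 5 constructs the mitotic list was higher (median 0.16, adjusted p = 6.0e-06, and adjusted p = 0.23 with an estimated correlation), and 752 genes differed, 419 higher and 333 lower. Of these 752, only 63 also differed from GFP in the same direction. Against GFP 483 genes changed, 238 raised and 245 lowered, and 75 of these changed at least 1.5-fold. The sign was the same in all 3 batches for 99.4% of them, but the same arrays made the calls, so that such shares are no independent check for any construct. Without ATM replicate 4 the count was 920, and it was 300, 286 and 303 without ATM replicate 1, ATM replicate 2 and GFP replicate 3. Of the included ATM arrays, replicate 4 had the lowest ATM level and also the highest lower quartile, 4.86 log2 against 4.56 to 4.74. Which of these goes with the higher count was not tested.

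On BCL2 arrays 1200 genes changed against GFP, of which 564 rose, 636 fell and 141 changed at least 1.5-fold. ANLN rose by 1.01 ± 0.16 log2 (SE, n = 6 against 6), TOP2A by 0.99 ± 0.15 and ANGPTL4, a secreted inhibitor of lipoprotein lipase, by 0.99 ± 0.08. ITGB6, an integrin subunit that activates TGF-beta, rose by 0.93 ± 0.16 and TNFSF10, the death ligand TRAIL, by 0.84 ± 0.17. Mitotic genes rose for 17 of 23 (21, and 1 lowered, adjusted over the list alone, adjusted p = 1.2e-30), and replication genes for 10 of 23, with 1 lowered (13 and 2 adjusted over the list alone, adjusted p = 8.4e-12). Matrix genes rose for 8 of 20 (9, and 1 lowered, adjusted over the list alone, adjusted p = 1.7e-07), among them LTBP2, a TGF-beta binding protein, by 0.58 ± 0.06 and MMP2, a gelatinase, by 0.57 ± 0.10. NF-kB targets rose for 7 of 30 (10, and 1 lowered, adjusted over the list alone, adjusted p = 5.4e-05). Heat shock genes fell for 14 of 15 (15 adjusted over the list alone, median -0.81, adjusted p = 3.4e-42).

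Among 26 genes of the BCL2 family and caspases, 1 rose and 2 fell on BCL2 arrays, and the list did not pass (adjusted p = 0.80). APAF1, the apoptosome scaffold, rose by 0.49 ± 0.12, and BCL2L1, a relative that inhibits apoptosis, fell by 0.34 ± 0.06. The p53 targets fell for 4 of 23 (8, and 1 raised, adjusted over the list alone, adjusted p = 1.9e-04, and adjusted p = 0.061 with an estimated correlation) and DNA damage genes rose for 5 of 23 (7 adjusted over the list alone, adjusted p = 3.9e-08, and adjusted p = 0.061 with an estimated correlation). NRF2 targets fell for 4 of 22 (adjusted p = 0.0020, and adjusted p = 0.37 with an estimated correlation), among them FTL, ferritin light chain, by 0.74 ± 0.16 and SLC7A11, the cystine transporter, by 0.73 ± 0.15. Unfolded protein response genes fell for 6 of 23 and rose for 1 (adjusted p = 0.037, and adjusted p = 0.46 with an estimated correlation), with DDIT3, an ATF4 target, falling by 0.51 ± 0.09. Interferon-stimulated genes rose for 2 of 30 (adjusted p = 0.033, and adjusted p = 0.57 with an estimated correlation), including OAS2 by 0.43 ± 0.09. Basal cell markers also passed (2 of 11 raised, adjusted p = 0.024, and adjusted p = 0.23 with an estimated correlation). Against the other 5 constructs 11 genes differed, among them ANGPTL4 (0.41 log2 higher, adjusted p = 3.2e-04), and 97.4% of the calls against GFP had the same sign in all 3 batches.

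On the arrays labelled GPX1, heat shock genes were among the largest decreases. HSPA1A fell by 2.84 ± 0.19 log2 (SE, n = 6 against 6), HSPA1B by 2.31 ± 0.11 and CHORDC1, an HSP90 co-chaperone, by 1.43 ± 0.23. Of 15 heat shock genes 13 fell (14 adjusted over the list alone, median -0.68, adjusted p = 1.1e-54). EGR1, an immediate early transcription factor, rose by 0.69 ± 0.09, NUAK1, a kinase, by 0.59 ± 0.07, and CA12, a carbonic anhydrase, by 0.58 ± 0.11. The p53 targets fell for 3 of 23 (5 adjusted over the list alone, adjusted p = 1.3e-05), including CDKN1A, the cyclin-dependent kinase inhibitor p21, by 0.43 ± 0.10. No NF-kB target passed in limma, against 4 of 30 raised when adjusted over the list alone, and the list test passed (adjusted p = 0.0020).

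Antioxidant genes moved down on GPX1 arrays where they moved. FTL fell by 0.88 ± 0.15 and TXNRD1, thioredoxin reductase, by 0.42 ± 0.09, with 3 of 22 NRF2 targets lowered (adjusted p = 0.0011, and adjusted p = 0.32 with an estimated correlation), and 1 of 28 glutathione and antioxidant enzymes fell (adjusted p = 0.024, and adjusted p = 0.57 with an estimated correlation). MT1X, a metallothionein, fell by 0.51 ± 0.09 as 1 of 10 metallothionein and zinc genes (adjusted p = 0.012, and adjusted p = 0.067 with an estimated correlation). Its difference from the other 5 constructs was -0.42 (adjusted p = 0.0075). Mitotic genes rose for 4 of 23 and fell for 1 (16 and 1 adjusted over the list alone, adjusted p = 3.9e-08, and adjusted p = 0.086 with an estimated correlation). CCNA2, cyclin A, fell by 0.35 ± 0.07, and MKI67 rose by 0.37 ± 0.09 (adjusted p = 0.062 without GFP replicate 3). Compared with the other 5 constructs, the mitotic list was lower on GPX1 arrays (median -0.18, adjusted p = 1.1e-15, and adjusted p = 0.022 with an estimated correlation).

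In all, 522 genes changed on GPX1 arrays, 160 raised and 362 lowered, with the same sign in all 3 batches for each of the 522, and 22 genes differed from the other 5 constructs. After median centring 55 of 334 changed genes were raised, and after quantile normalization 251 of 659. The count was 343, 321 and 339 without GFP replicate 3, GFP replicate 8 and GPX1 replicate 2. Matrix genes passed with 5 of 20 raised (adjusted p = 0.0020, and adjusted p = 0.16 with an estimated correlation), and ribosomal protein genes passed as lower with no single member called by limma (median -0.11, adjusted p = 6.7e-05, and adjusted p = 0.25 with an estimated correlation).

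On IKBKB arrays the NF-kB targets rose. TNFAIP3, the feedback inhibitor A20, rose by 1.02 ± 0.08 log2 (SE, n = 6 against 6, adjusted p = 1.4e-10), CXCL8 by 0.96 ± 0.08, ICAM1, a leukocyte adhesion molecule, by 0.76 ± 0.08, and CXCL2, a chemokine, by 0.75 ± 0.14. Of 30 targets 14 rose, none fell and 16 did not pass (20 adjusted over the list alone, median 0.28, adjusted p = 4.4e-31). Against the other 5 constructs 11 of the 30 were higher (adjusted p = 8.9e-42), including TNFAIP3 by 0.79 (adjusted p = 8.1e-10), and both tests held with an estimated correlation. EDN1, the peptide endothelin, rose by 0.91 ± 0.10 against GFP and was 0.42 higher than in the other 5 constructs (adjusted p = 0.0075). Among genes outside the naming rule, chosen after their values were seen, the cytokine IL6 rose by 0.61 ± 0.10 against GFP and was 0.80 higher than in the other 5 constructs (adjusted p = 1.1e-08).

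The mitotic list also rose on IKBKB arrays, for 17 of 23 genes (20 adjusted over the list alone, adjusted p = 2.3e-32), with TOP2A up by 0.93 ± 0.15, and replication genes rose for 9 of 23 (16, and 1 lowered, adjusted over the list alone, adjusted p = 1.1e-13). DNA damage genes rose for 6 of 23 (8 adjusted over the list alone, adjusted p = 9.4e-10). Heat shock genes fell for 13 of 15 (15 adjusted over the list alone, adjusted p = 6.0e-44). Squamous differentiation genes fell for 3 of 22 (6 adjusted over the list alone, median -0.22, adjusted p = 8.9e-05, and adjusted p = 0.25 with an estimated correlation), and the list was also lower than in the other 5 constructs (adjusted p = 2.5e-05, and adjusted p = 0.26 with an estimated correlation). Genes raised in the airway epithelium of smokers fell for 2 of 24 (adjusted p = 0.018, and adjusted p = 0.45 with an estimated correlation), including UCHL1, a ubiquitin hydrolase, by 0.64 ± 0.09. In all, 686 genes changed, 319 raised, 367 lowered and 109 by at least 1.5-fold, and all 686 had the same sign in the 3 batches. From the other 5 constructs 26 genes differed, 19 higher and 7 lower.

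On NOS2 arrays, genes of the extracellular matrix rose. MMP2 rose by 0.66 ± 0.10 log2 (SE, n = 5 against 6), LTBP2 by 0.57 ± 0.07 and TNC, the matrix glycoprotein tenascin C, which was not on the list, by 0.74 ± 0.13. Of 20 matrix and TGF-beta response genes 7 rose and 13 did not pass (9, and 1 lowered, adjusted over the list alone, median 0.17, adjusted p = 1.3e-07). ANGPTL4 rose by 0.84 ± 0.08 and CA12 by 0.72 ± 0.11. LTBP2 and ANGPTL4 rose in all 6 constructs, and the matrix list also passed in BCL2, GPX1 and SIRT1. On GFP arrays 7 of its 20 genes were lower than in the mean of the 6 constructs. The rise of the list against GFP therefore need not be particular to NOS2. From the other 5 constructs only 11 genes differed on NOS2 arrays, 7 higher and 4 lower. Mitotic genes rose for 7 of 23 (14, and 1 lowered, adjusted over the list alone, adjusted p = 5.1e-14), and the list was lower than in the other 5 constructs (median -0.12, adjusted p = 4.2e-05, and adjusted p = 0.30 with an estimated correlation). Heat shock genes fell for 13 of 15 (14 adjusted over the list alone, median -0.65, adjusted p = 1.1e-35), with HSPA1B falling by 1.56 ± 0.12 against GFP and standing 0.58 higher than in the other 5 constructs (adjusted p = 0.0026).

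The p53 targets fell on NOS2 arrays for 4 of 23 (5 adjusted over the list alone, adjusted p = 5.6e-06), with GDF15 falling by 0.44 ± 0.09. Hypoxia and glycolysis genes rose for 4 of 18, among them ADM, adrenomedullin, by 0.41 ± 0.07 and SLC2A1, the glucose transporter, by 0.40 ± 0.09, although the list did not pass (adjusted p = 0.20). Basal cell markers rose for 2 of 11 (3 adjusted over the list alone, adjusted p = 0.0021, and adjusted p = 0.071 with an estimated correlation), including ITGB4, an integrin of hemidesmosomes, by 0.38 ± 0.08. Fibroblast markers passed with 1 of 13 raised, FBLN1, a matrix glycoprotein, by 0.29 ± 0.06 (adjusted p = 0.031, and adjusted p = 0.50 with an estimated correlation). Against GFP 722 genes changed, 305 raised, 417 lowered and 83 by at least 1.5-fold, of which 99.0% had the same sign in all 3 batches. After quantile normalization 440 of 833 changed genes were raised and after median centring 151 of 441, and without GFP replicate 8 the count was 448.

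On SIRT1 arrays, KRT75, a hair follicle keratin, rose by 1.10 ± 0.11 log2 (SE, n = 5 against 6), KRT6C, a keratin of stressed epidermis, by 1.01 ± 0.21, MMP10, a stromelysin, by 1.04 ± 0.18, and CA12 by 1.15 ± 0.11. Each was also higher than in the other 5 constructs, by 0.58, 1.09, 0.74 and 0.54 (adjusted p = 3.9e-05, 1.2e-04, 0.0021 and 2.7e-04). Squamous differentiation genes rose for 1 of 22 (1 adjusted over the list alone), and the list did not pass (adjusted p = 0.35), while 3 were higher than in the other 5 constructs (adjusted p = 2.4e-05, and adjusted p = 0.26 with an estimated correlation). NRF2 targets rose for 3 of 22 (7, and 2 lowered, adjusted over the list alone, adjusted p = 0.024, and adjusted p = 0.56 with an estimated correlation). Against the other 5 constructs 5 of the 22 were higher (adjusted p = 2.8e-12, and adjusted p = 0.028 with an estimated correlation). AKR1C2 and AKR1C3, aldo-keto reductases, rose by 0.46 ± 0.11 and 0.63 ± 0.15 (for AKR1C3, adjusted p = 0.064 without SIRT1 replicate 7). The difference for AKR1C2 was 0.19, 0.23 and 0.88 in batches 1, 2 and 4.

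Genes raised in the airway of smokers, a list that shares 13 members with the NRF2 list, rose for 4 of 24 on SIRT1 arrays and fell for 1 (9 and 2 adjusted over the list alone, adjusted p = 7.7e-04, and adjusted p = 0.23 with an estimated correlation). In the comparison with the other 5 constructs 6 of the 24 were higher (adjusted p = 7.0e-13, and adjusted p = 0.011 with an estimated correlation). FOXO and SIRT1 related genes rose for 3 of 20 (adjusted p = 0.016, and adjusted p = 0.16 with an estimated correlation), among them SESN3, a sestrin, by 0.89 ± 0.15 and PIK3IP1, an inhibitor of PI3-kinase, by 0.65 ± 0.09, and the list was higher than in the other 5 constructs (adjusted p = 1.5e-06, and adjusted p = 0.0088 with an estimated correlation). Hypoxia genes rose for 3 of 18 (adjusted p = 0.0028, and adjusted p = 0.25 with an estimated correlation), including ADM by 0.56 ± 0.07. Matrix genes rose for 7 of 20 (9, and 1 lowered, adjusted over the list alone, adjusted p = 9.5e-07) and basal cell markers for 2 of 11 (4 adjusted over the list alone, adjusted p = 1.3e-05). NF-kB targets rose for 5 of 30 and fell for 1 (8 and 2 adjusted over the list alone, adjusted p = 0.022). Against the mean of the other 5 constructs, which for each construct but IKBKB includes the IKBKB arrays, the NF-kB list was lower in SIRT1 (median -0.09, adjusted p = 8.7e-04), NOS2 (median -0.08, adjusted p = 8.9e-07) and GPX1 (median -0.02, adjusted p = 0.0044), and did not pass in ATM (adjusted p = 0.84) or BCL2 (adjusted p = 0.41). Mitotic genes rose for 10 of 23 (18, and 1 lowered, adjusted over the list alone, adjusted p = 5.0e-19) and heat shock genes fell for 12 of 15 (13 adjusted over the list alone, adjusted p = 3.0e-35).

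In all, 1088 genes changed on SIRT1 arrays, 690 raised, 398 lowered and 124 by at least 1.5-fold, with the same sign in all 3 batches for 97.8% of them. From the other 5 constructs 426 genes differed, 385 higher and 41 lower. Over all 6 constructs, camera passed 69 of the 168 list tests, 41 raised and 28 lowered, and 29 of these held with an estimated correlation. The lists of immediate early genes, mitochondrial and fatty acid oxidation genes, the BCL2 family, housekeeping genes, and ciliated, secretory, leukocyte and endothelial markers passed camera in no construct. No named gene reversed under quantile normalization or median centring, and the median change of all genes lay between -0.04 and 0.04 log2.

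**Figure D2:**
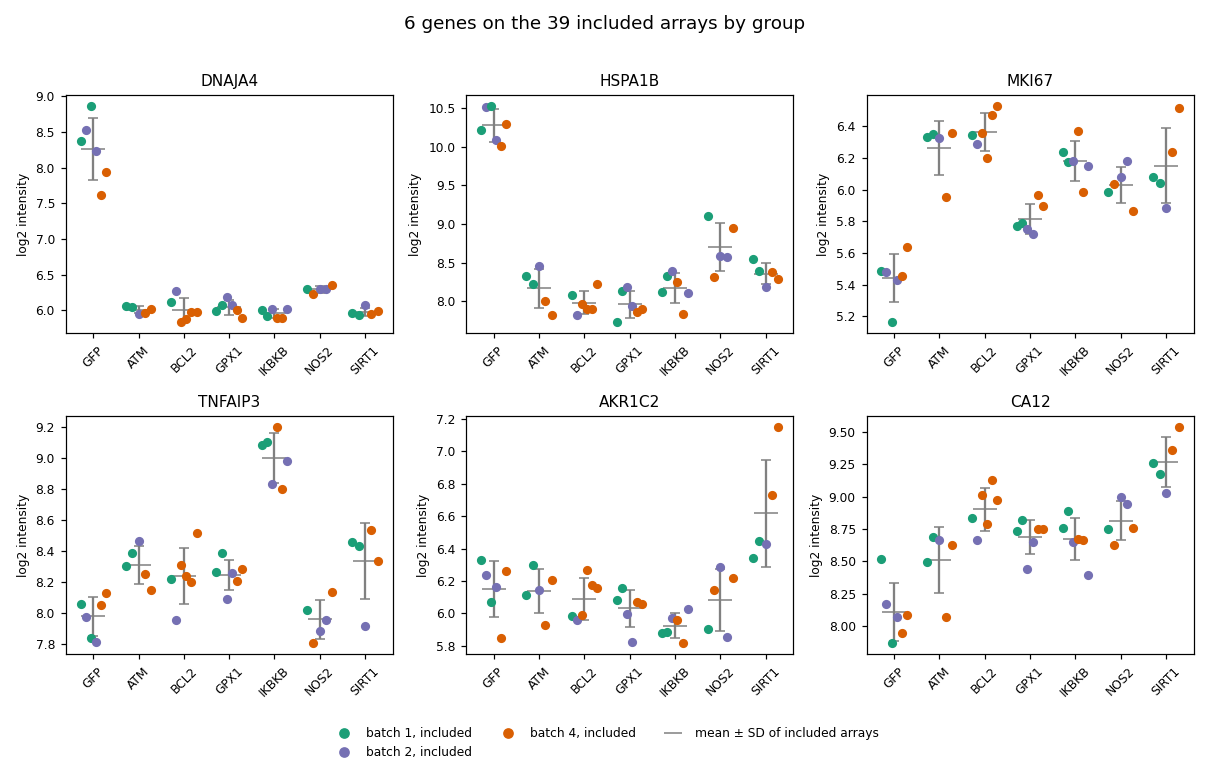
Level (log2 RMA intensity) of DNAJA4, HSPA1B, MKI67, TNFAIP3, AKR1C2 and CA12 on the 39 included arrays, by group, with circles coloured by batch and bars for the mean ± SD. For DNAJA4 the lowest GFP array, at 7.62, lies above the highest construct array, at 6.35, TNFAIP3 is highest on IKBKB arrays, and AKR1C2 and CA12 are highest on SIRT1 arrays.

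Each construct was also set against all 6 other groups together, GFP included. There 526 genes differed for ATM, 58 for BCL2, 19 for GPX1, 49 for IKBKB, 17 for NOS2 and 495 for SIRT1. In the same direction against GFP were 103, 56, 11, 42, 12 and 338 of these. All 6 counts moved by more than 1.5 times without 1 array. The ATM count was 61 without ATM replicate 1, 88 without replicate 2, 1688 without replicate 4 and 349 without replicate 7. The SIRT1 count was 325, 230 and 265 without SIRT1 replicates 1, 5 and 7. For BCL2 it was 34, 23, 32, 31 and 36 without replicates 1, 5, 6, 7 and 8, and for GPX1 12, 11, 10 and 11 without replicates 1, 2, 3 and 4. For IKBKB it was 27, 25, 26 and 28 without replicates 1, 2, 5 and 7, and for NOS2 7, 4, 3, 3 and 9 without replicates 1, 2, 3, 4 and 7.

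Whether an effect differed between batches was tested by interaction. For ATM 2 genes passed (6962 at an unadjusted p under 0.05), 1 of them not named here and the other SNORA49, a small nucleolar RNA outside the naming rule, at 0.98, -0.28 and -0.87 log2 in batches 1, 2 and 4 (adjusted p = 0.035). With limma, 0 genes passed for BCL2 (1495 unadjusted), GPX1 (782), IKBKB (1155), NOS2 (1250) and SIRT1 (3789). By chance a share of 0.05 of the 23536 genes would have such an unadjusted p, and the ATM and SIRT1 counts were well above it. Over all genes, the difference from GFP had the same sign in all 3 batches for 18.2% in ATM and 22.2% in SIRT1, where chance gives 25%. In the other constructs the share was 30.2% to 41.7%. The few genes passing therefore do not show that the ATM effect was uniform across batches. Batches differed by 4 genes between 2 and 1, 183 between 4 and 1 and 657 between 4 and 2.

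The 12 arrays of batch 3 differed from the rest in 4568 genes, 2490 higher and 2078 lower. COX7C, a respiratory chain subunit, was 2.49 ± 0.15 log2 higher (SE, n = 12 against 40), HSPE1, the mitochondrial HSP10, 2.06 ± 0.19, and RPS21, a ribosomal protein, 1.56 ± 0.06, all chosen after their values were seen. Ribosomal protein genes were higher for 13 of 17 (adjusted p = 3.7e-15) and glutathione and antioxidant enzymes for 12 of 28 (adjusted p = 2.0e-06), while immediate early genes were lower for 6 of 16 (adjusted p = 0.0051). In batch 3, 6 of the 12 arrays carried a level of DNAJA4, NOS2, BCL2 or GPX1P1 that contradicted the label. The cutoffs lay between the groups of the included arrays, so those arrays could not contradict their labels and give no comparison. No marker was used for ATM, IKBKB or SIRT1, so exchanges among these were not counted. The IKBKB level set the included IKBKB arrays apart from the rest by a narrow margin, 7.86 against 7.77. In batch 3 it was 7.42 on the only array labelled IKBKB and 7.82 on ATM replicate 6. The count of 6 may therefore be too low. As labelled, construct minus GFP in batch 3 had the same sign as the included arrays for 62.2% (IKBKB) to 82.3% (SIRT1) of the genes called. Over all genes the 2 sets of differences correlated at 0.30 (ATM), 0.31 (BCL2), -0.22 (GPX1), -0.16 (IKBKB), 0.024 (NOS2) and 0.33 (SIRT1). The reference held the array labelled GFP replicate 6, with NOS2 at 11.17, so these values do not serve as a check of the calls.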

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

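Chosen after the result was seen were the tests of a single GFP array, of a rise in GFP against a fall in each construct, of a mixture of 2 samples in batch 3, and those on GPX1 and GPX1P1. Chance singles out about 1 in 20 groups of samples, and 14 of the 126 groups tested held a sample far from the others. Of the 12 arrays of batch 3, 6 account for many of these.

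Several arrays of batch 3 carried the level of another group. The array labelled GFP replicate 6 had NOS2 at 11.17, where the other GFP arrays lay between 4.71 and 5.04, and that labelled NOS2 replicate 6 had 5.31 where the other NOS2 arrays lay between 11.13 and 11.41. The array labelled BCL2 replicate 3 had BCL2 at 4.96 (others 6.09 to 6.75) and GPX1P1 at 11.13 (others 6.43 to 7.27). The array labelled GPX1 replicate 5 had GPX1P1 at 7.12 (others 11.02 to 11.56). The array labelled SIRT1 replicate 6 had BCL2 at 6.77 (others 4.49 to 5.33). The array labelled ATM replicate 5 had a mean over the heat shock genes of 8.44, where the other ATM arrays lay between 7.28 and 7.76. Also far from their groups in batch 3 were IKBKB replicate 4, with IKBKB at 7.42 (others 7.86 to 8.14), and NOS2 replicate 5, with SIRT1 at 7.14 (others 6.61 to 6.75). NOS2 replicate 5 carried NOS2 at 11.41, the level of its label, and had the lowest lower quartile of all 52 arrays, 4.41 log2. The included groups overlapped for SIRT1, so its SIRT1 level does not point to another group. The NOS2, BCL2 and GPX1P1 levels of 11.17, 6.77 and 11.13 on the arrays labelled GFP, SIRT1 and BCL2 are also signals in data that the comparisons did not use, above the level of the GFP arrays for each gene.

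Each of the 4 markers DNAJA4, NOS2, BCL2 and GPX1P1 was carried by 2 arrays of batch 3, the number labelled with the matching group, but for each only 1 array had both the marker and the label. A mixture of 2 samples on 1 array was argued against, since the wrong marker stood at or above the lowest included array of its own group in 4 of 4 arrays. Labels permuted among the arrays of batch 3 may account for the pattern. A score over 1114 other genes that separate GFP from the constructs, without chaperones, was highest on the 2 arrays with high DNAJA4, at 0.213 and 0.204 against 0.032 for the next array, a gap of 0.17. Which array belongs to which group cannot be settled for those carrying no marker, and no biological explanation was tested.

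Heat shock genes were higher on GFP arrays than in all 6 constructs. A single GFP array or batch was argued against, since the lowest GFP array lay 0.50 log2 above the highest construct array in the list mean. Compression of the signal across an array was argued against as well, because the median difference was 0.64 with the lower quartile in the model and 0.63 without it. Whether the genes rose in GFP cells or fell under each construct cannot be told apart, as no uninfected arrays were used here; the 6 construct means spanned 0.27 log2, against a gap of 0.99 to GFP. A response to GFP protein, or to that virus preparation, is a candidate explanation that stays open.

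Arrays labelled GPX1 had an unchanged call for GPX1 and a high level of GPX1P1. A ceiling of the GPX1 probe set stays open: on each of these arrays at least 80 values lay more than 1 log2 unit above it, but other probe sets do not show where this one saturates. A GPX1 transcript from the virus that is read by the GPX1P1 probe set may account for the pattern, as the lowest GPX1 array lay 2.38 log2 above the highest other array. Transcription of the pseudogene itself would give the same value, so these cannot be told apart without the probe sequences, which were not used here.

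Among the included arrays, ATM replicate 4 had ATM at 6.56, far from the other ATM arrays at 7.13 to 7.24. Its lower quartile, 4.86 log2, was also the highest of these ATM arrays. GPX1 stood at 8.68 on BCL2 replicate 8, against 8.86 to 8.94 on the other included BCL2 arrays and 8.82 to 8.94 on all others labelled BCL2. SIRT1 stood at 6.63 on IKBKB replicate 6, against 6.88 to 6.95 on the other IKBKB arrays, both included and labelled. By the interaction test, the effect of ATM differed between batches for 2 genes past the threshold. At an unadjusted p under 0.05 it differed for 6962 of 23536 genes.

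Each count was set against 100 splits of the same arrays into groups of the same sizes, the real one included. The real count was reached in 1 to 3 of the 100 splits. No allowance was made for the number of counts tested, and the splits did not keep labels within batches. Where more than 1 split reached the real count, chance is therefore not excluded. Where 1 did, no other split gave as many genes. The real count of genes changed against GFP was reached in 3 splits for ATM (483, highest other 5477), 1 for BCL2 (1200, highest other 527), 1 for GPX1 (522, highest other 169), 1 for IKBKB (686, highest other 283), 1 for NOS2 (722, highest other 183) and 2 for SIRT1 (1088, highest other 1141). For genes set apart from all other groups it was reached in 2 splits for ATM (526, highest other 12071), 1 for BCL2 (58, highest other 0), 1 for GPX1 (19, highest other 2), 1 for IKBKB (49, highest other 1), 2 for NOS2 (17, highest other 4612) and 3 for SIRT1 (495, highest other 9686). For GFP against the 6 constructs it was reached in 1 (1219, highest other 1). For batches it was reached in 2 for batch 3 against the rest (4568, highest other 6090), 1 for 2 against 1 (4, highest other 1), 2 for 4 against 1 (183, highest other 2191) and 2 for 4 against 2 (657, highest other 16084). Splits that called several times the real count occurred for ATM against GFP, for ATM, NOS2 and SIRT1 set apart, and for batch 4 against 1 and against 2, and point to a structure of the samples, which was not tested further. The first component of all 52 arrays held 54.9% of the variance and followed the lower quartile of the array at r = 0.976.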

How the results depend on the processing

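The settings chosen after the data were seen were the lower quartile covariate, each batch alone, the list tests against the other 5 constructs, and GFP against the 6 constructs. Of 277 calls on named genes, none reversed under an alternative set beforehand; 89 were lost with only the arrays of 1 construct and GFP, 86 with all 52 arrays, 62 with median centring, 30 with the replicate block, 29 with quantile normalization, and 13 without the batch term. Leaving out 1 array at a time lost the call in 299 of 3187 fits, and 58 of the 277 calls were lost without at least 1 array. With the lower quartile covariate, 4701 of 4701 calls against GFP were kept. Of the 80 list tests that passed camera or had at least 3 members called, 18 no longer passed with that covariate and 2 newly passed. How far signal over background limits small changes was not tested. Where no reason is given, the cause was not tested.

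Genes changed against GFP moved by more than 1.5 times as follows. With only the 2 groups' arrays, and so fewer samples, there were 87 for ATM, 336 for BCL2, 361 for IKBKB, 381 for NOS2 and 359 for SIRT1. With all 52 arrays there were 184 for ATM, 259 for GPX1, 330 for IKBKB and 279 for NOS2. With the replicate block, which takes same-numbered arrays as paired although their numbers did not pair them, there were 933 for ATM, 779 for BCL2 and 440 for IKBKB. Median centring gave 334 for GPX1 and 441 for NOS2, and leaving out the dimmer 50% of the genes gave 302 for ATM. Array weights gave 7082, 1980, 1340, 4323, 1727 and 2239 for ATM, BCL2, GPX1, IKBKB, NOS2 and SIRT1, in that order here and below. The lower quartile covariate gave 1269, 3334, 1675, 1700, 2029 and 2525. Requiring a change of at least 1.5-fold gave 75, 141, 77, 109, 83 and 124. With the 1 to 4 arrays per group of a single batch, there were 5603, 31, 24, 1617, 8 and 67 in batch 1, 4, 32, 43, 29, 6 and 19 in batch 2, and 18, 198, 13, 21, 24 and 188 in batch 4; a lone array was assumed to vary like the other groups.

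The ATM level passed with array weights (0.48) and in batch 1 (0.72) and reversed in batch 4 (-0.042), and GPX1 reversed in batch 2 (0.13). IKBKB did not pass in batches 2 and 4 alone (0.55 and 0.38). SIRT1 did not pass with only its arrays and GFP (0.33), with median centring (0.36) or in batches 1, 2 and 4 alone (0.19, 0.26 and 0.51). Of named genes, HERC6 on BCL2 arrays reversed in batch 2 (-0.0049) and ADH7 on SIRT1 arrays in batch 1 (-0.043). List tests fell from 69 to 29 with an estimated correlation, and 50 passed with fry. Of the 80 list tests followed, 40 no longer passed with an estimated correlation, 22 with fry and 16 with all 52 arrays. The other alternatives set beforehand lost 5 to 11 of them. Genes set apart were 11 for BCL2, 26 for IKBKB and 11 for NOS2 against the other 5 constructs, 320 for ATM and 9 for NOS2 without the batch term, and 1580, 795, 44, 195, 214 and 1228 with the lower quartile covariate. GFP against the 6 constructs gave 3030 with that covariate. On GFP arrays alone batches differed by 164 genes (3 against the rest), 0 (2 against 1), 1 (4 against 1) and 0 (4 against 2) in limma, with 2037, 561, 2436 and 1797 at an unadjusted p under 0.05. The interaction for ATM gave 1 gene in batches 1 and 4.

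Leaving out 1 array at a time gave 286 to 920 genes for ATM, 855 to 1494 for BCL2, 321 to 626 for GPX1, 460 to 785 for IKBKB, 448 to 986 for NOS2 and 754 to 1322 for SIRT1. Counts moved by more than 1.5 times without ATM replicates 1 (300), 2 (286) and 4 (920) or GFP replicate 3 (303) for ATM, without GFP replicates 3 (343) and 8 (321) or GPX1 replicate 2 (339) for GPX1, and without GFP replicate 8 (448) for NOS2. Virus-borne genes gave 0.25 to 0.50 for ATM, 1.72 to 1.80 for BCL2, -0.17 to -0.07 for GPX1, 0.45 to 0.51 for IKBKB, 6.36 to 6.45 for NOS2 and 0.29 to 0.37 for SIRT1, which did not pass without SIRT1 replicate 5 (0.29). Genes set apart gave 61 to 1688 for ATM (61, 88, 1688 and 349 without replicates 1, 2, 4 and 7), 23 to 55 for BCL2 (34, 23, 32, 31 and 36 without replicates 1, 5, 6, 7 and 8), 10 to 21 for GPX1 (12, 11, 10 and 11 without replicates 1, 2, 3 and 4), 25 to 53 for IKBKB (27, 25, 26 and 28 without replicates 1, 2, 5 and 7), 3 to 9 for NOS2 (7, 4, 3, 3 and 9 without replicates 1, 2, 3, 4 and 7) and 230 to 568 for SIRT1 (325, 230 and 265 without replicates 1, 5 and 7). GFP against the 6 constructs gave 807 (without GFP replicate 3) to 1369.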

Other observations

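The unfolded protein response and ATF4 list was lower against GFP with adjusted p = 0.033 in GPX1, 0.031 in NOS2 and 0.019 in SIRT1 arrays (adjusted p = 0.45, 0.44 and 0.37 with an estimated correlation). Members lowered numbered 5, 5 and 4 of 23, and 1 rose in GPX1. DDIT3, a transcription factor of that response, fell by 0.54 ± 0.08 log2 in GPX1 (SE, n = 6 against 6), by 0.48 ± 0.09 in NOS2 and by 0.38 ± 0.09 in SIRT1 (n = 5 against 6). ASNS, asparagine synthetase, fell by 0.35 ± 0.07, 0.32 ± 0.07 and 0.44 ± 0.07. All share the same 6 GFP arrays, on which the list was higher than in the mean of the 6 constructs (adjusted p = 0.024, and adjusted p = 0.44 with an estimated correlation), so that the constructs are not independent here. The tests of each construct against GFP were set beforehand, and that of GFP against the 6 constructs was not.

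UCHL1, which is on the list of genes raised in smokers, fell in all 6 constructs, by 0.49 to 0.81 log2, and was 0.64 higher in GFP than in the mean of the 6 constructs. BCL2L11, a BCL2 family member that promotes apoptosis, rose by 0.35 ± 0.08 in SIRT1 arrays and was 0.31 higher than in the other 5 constructs (adjusted p = 0.0026). HEPHL1, a ferroxidase, rose there by 0.98 ± 0.11 and was 0.75 higher than in the other 5 constructs (adjusted p = 3.2e-06).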
